A study of Mus musculus with 18 samples.

How the data were processed

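RNA was taken from brain cortex and from the interparietal bone of the skull of BALB/c mice, 18 libraries in 6 groups of 3. Per the labels' protocols, RNA was extracted with TRIzol and treated with DNase, messenger RNA was selected by its poly(A) tail, and libraries were made with NEBNext kits and read as Illumina pairs of 150 bases from each end. The submitters' processing notes name HISAT2 2.1.0 and the build mm10. The counting program, its annotation and its strand setting are not given in the sources used here. The deposited table holds counts, raw read counts per gene, whole numbers from 0 up; no normalization had been applied. It has 26783 lines for 25918 gene names, because 49 names stand in 16 or 81 identical copies; the 865 surplus copies were removed. Each column was assigned to its group by its name, and none was left over.

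Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Each tissue was fitted on its own over its 9 libraries, with filterByExpr by group, TMM factors, estimateDisp and a robust quasi-likelihood fit, and each pair of groups was tested two-sided. The difference between the day 2 responses of brain and skull was an interaction contrast over the 12 libraries of controls and day 2, and the control groups were compared over their 6 libraries. P-values were adjusted by Benjamini-Hochberg over the genes of a comparison and a gene was called below 0.05. Shared genes at day 2 were counted per direction and set against the product of the 2 counts over the genes tested in both, with a Fisher exact test. Fitted log2 changes use a prior count of 0.125. A fold against a group with no count is given as at least its value against a floor of 3 counts over the group; with 1 to 3 counts it is a ratio with a 95% interval. These intervals and floors cover counting error alone.

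The lists, 30 of cell types and 23 of processes with 634 genes in all, were written before the data were examined, as were the tests, the rule for naming genes and most of the alternatives; 614 of the genes are in the table. Lists with at least 4 measured members were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, with the correlation estimated per list and with fry as alternatives. The lists described were picked from those tested after the results were seen. Camera called 30 of 50 lists in brain at day 2, 32 of 50 at day 6 and 24 of 50 between these days. In skull it called 30 of 52 at day 2, 30 of 52 at day 4 and 27 of 52 between these days, with 28 of 52 for the difference of responses and 39 of 52 for the control groups.

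The genes named were the 8 with the largest rise and the 8 with the largest fall per comparison among called genes with a mean of at least 5 CPM in the higher group and no overlap of the libraries of the groups. The condition on overlap was not applied to the difference of responses. Unnamed loci, antigen receptor segments, microRNA genes and small nucleolar RNA genes were skipped. Up to 4 members of each described list with the smallest adjusted p, and members that went against their list, were named as well; Gfap in brain at day 2, members named because they did not pass the test, and genes given as examples in the shared response were chosen after their values were seen. A few genes that this rule would name are left out of the text.

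The alternatives fixed then were RLE and upper quartile factors, no filter and a stricter filter (1 CPM in 3 libraries and 90 counts in all), DESeq2, limma voom, a replicate block, a fit of the compared groups alone, a 2-fold minimum, an adjusted p of 0.01, library sizes without haemoglobin and the 20 most abundant genes, and leaving out each library in turn. The fit without genes at least 4-fold higher in brain controls and TMM factors within each tissue were added after seeing the data. No label says that libraries with the same number share an animal or a day, or that each library is a separate animal, so that a p-value here measures the spread between these libraries.

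The procedure was tested on simulated data at the depth and spread of these libraries. Of genes with a simulated 2-fold change, 62.1% were called in brain at day 2, 41.8% in skull at day 2 and 10.8% in the difference of responses. At 4-fold these were 93.4%, 84.6% and 63.1%. Few genes were changed in the simulation, such as 66 at 2-fold among 18242 tested in brain at day 2. In the data, 4485 of 18151 were called there. Adjustment is stricter when few genes change, so the shares recovered do not give the recovery in the data. False calls made up 9.93%, 5.61% and 3.77% of all calls, so that the shares in brain and in skull at day 2 lay above the nominal 5%. A raised list was recovered in each case and 0 of 50 random lists were called. Each simulated gene was drawn on its own, and the random lists held unchanged genes only. The lists called thus say nothing about false calls of lists whose genes vary together.

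Copies that are nearly identical in sequence, such as Hbb-bs and Hbb-bt, share reads, and their separate values are uncertain. The exons of Aldoa, Ankrd55, Car9, Ccna2, Col10a1, Cp, Cyp51, Fam227b, P2ry12, Prg4 and Stab1 overlap those of another gene with more than 5% of their own counts, and with the strand not stated part of their counts is uncertain. Aldoa has no single position in GENCODE M21. Transcripts not selected by a poly(A) tail, splicing and variants were not analysed here.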

Results

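Messenger RNA was sequenced from the cerebral cortex and the interparietal bone of the skull of BALB/c mice, either controls or animals with ischemic injury, to follow expression in both tissues after the injury. There were 18 libraries in 6 groups of 3: cortex, called brain here, from controls and at days 2 and 6 after injury, and skull from controls and at days 2 and 4. Per the labels, the tissue taken included the ischemic and the peri-ischemic region. Total counts per library were 23673255 to 27654269 in brain controls, 17199036 to 18476057 in brain at day 2 and 13005050 to 22236424 in brain at day 6. In skull they were 13398631 to 14765111 in controls, 15113558 to 15382973 at day 2 and 13142770 to 15445503 at day 4. Levels are mean CPM (the TMM-normalised scale of edgeR) ± SD over the 3 libraries of a group, changes are log2 fold changes ± the standard error of the edgeR fit, and positions are on mm10 from GENCODE M21. Over all genes tested, the libraries of the groups compared did not overlap in 30.5% to 47.7% of genes in the 6 comparisons within a tissue and in 76.7% between the control groups, where chance gives 10%.

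The control libraries carried the transcripts of their tissues. Brain controls were rich in Slc17a7, the vesicular glutamate transporter of excitatory neurons (1014 ± 36.2 CPM against 48.5 ± 23.1 in skull, log2 difference 4.39 ± 0.43, adjusted p = 1.91e-04), and in Mbp, a myelin protein (4.23 ± 0.34, adjusted p = 5.88e-05). Skull controls were rich in the bone collagen gene Col1a1 (31020 CPM against 10.6 in brain, log2 difference -11.52 ± 0.51, adjusted p = 4.48e-06), the neutrophil gene S100a9 (-10.18, adjusted p = 4.49e-06) and the beta-globin Hbb-bs (-7.88, adjusted p = 1.07e-06). Of 18173 genes tested, 12891 differed between the control groups, 6277 higher in brain and 6614 higher in skull. All 11 measured osteoblast genes were lower in brain (11 adjusted over the list alone), with a median log2 difference of -7.64 (camera adjusted p = 4.97e-16), and the adjusted p = 0.0893 with an estimated correlation. All 16 measured genes of synaptic transmission were higher (16 adjusted over the list alone), with a median of 3.75 (camera adjusted p = 6.9e-08, adjusted p = 0.172 with an estimated correlation).

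At day 2 after injury, the cortex carried high levels of inflammatory and glial transcripts. Lcn2, an iron-binding protein secreted by reactive glia and neutrophils, rose from 0.126 ± 0.151 to 184 ± 86.8 CPM (log2 change 10.50 ± 0.61, adjusted p = 2.18e-05; chromosome 2, 32384633 to 32388252). Gfap, the intermediate filament of astrocytes, rose from 204 ± 60.9 to 2982 ± 458 CPM (adjusted p = 1.78e-06). The monocyte attractant Ccl2 was 686-fold higher (95% counting interval 190 to 5674, 2 counts in the controls; adjusted p = 4.03e-06; chromosome 11, 82035571 to 82037453), and the acute phase gene Saa3, with no count in the controls, was at least 430-fold higher (adjusted p = 5.15e-06; chromosome 7, 46711998 to 46715700). The transcripts that fell most changed less, and the 8 leading ones fell by 1.66 to 2.65 on the log2 scale. Of 18151 genes tested, 4485 changed at day 2, 2671 up and 1814 down. Of these, 1637 changed by at least 2-fold, 1462 up and 175 down, and 2616 passed an adjusted p of 0.01.

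All 17 measured reactive astrocyte genes rose at day 2 (17 adjusted over the list alone), with a median log2 change of 3.85 (camera adjusted p = 5.88e-79). Among them were the oncostatin M receptor Osmr (3.74 ± 0.19), the pentraxin Ptx3 (8.62 ± 0.41), the lipid receptor S1pr3 (3.35 ± 0.18) and the protease inhibitor Timp1 (5.69 ± 0.30). Of 18 cytokines and chemokines, 17 rose (18 adjusted over the list alone). Leading members were Ccl12 (8.31 ± 0.43), Cxcl1 (459-fold, interval 157 to 2228) and Ccl7 (193-fold, interval 65.6 to 939). Il1rn did not pass the test. The median was 5.11, or 5.19 with genes near 0 counts set to their bounds (camera adjusted p = 2.99e-29). Of 10 measured neutrophil genes, 8 rose (9 adjusted over the list alone). Examples were the chemokine receptor Cxcr2 (642-fold, interval 115 to 25422), Csf3r (2.35 ± 0.20) and S100a9 (5.50 ± 0.44). The median was 3.94, or 3.39 at the bounds (camera adjusted p = 2.7e-12). Leukocyte trafficking genes followed, 11 of 14 up (11 adjusted over the list alone) with a median of 3.17 (camera adjusted p = 6.48e-18). Ccr2, the receptor for Ccl2, rose by 4.83 ± 0.36, and Selp, the endothelial and platelet selectin, was at least 140-fold higher. All 20 interferon-stimulated genes rose (20 adjusted over the list alone; median 2.67, camera adjusted p = 1.98e-26). In front stood Ifitm3 (3.54 ± 0.24) and Oasl2 (3.76 ± 0.31). Of 11 complement genes 10 rose (10 adjusted over the list alone; median 2.45, camera adjusted p = 1.66e-26). C3 changed by 6.85 ± 0.37 and C4b by 2.80 ± 0.21. These 6 lists were also called with an estimated correlation (adjusted p = 0.0197 to 0.0452).

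All 20 cell cycle genes rose (20 adjusted over the list alone), with a median log2 change of 3.21 (camera adjusted p = 8.1e-34), but with an estimated correlation the adjusted p = 0.0573. The replication helicase subunits Mcm3 (3.10 ± 0.21) and Mcm6 (3.49 ± 0.24) and the kinase Cdk1 (5.59 ± 0.44) led the list. Genes named for homeostatic microglia moved in both directions: 7 of 12 rose and 2 fell (8 and 2 adjusted over the list alone), with a median of 0.90 (camera adjusted p = 4.83e-06, adjusted p = 0.241 with an estimated correlation). Fcrls rose from 6.27 ± 0.346 to 58.9 ± 6.67 CPM. The purinergic receptor P2ry12 fell by 0.49 (adjusted p = 6.68e-03) and Siglech fell by 0.68 (adjusted p = 7.97e-03). Border macrophage genes rose in 8 of 9 cases (9 adjusted over the list alone; median 2.80, camera adjusted p = 5.64e-07, adjusted p = 0.194 with an estimated correlation). Among them were the scavenger receptors Mrc1 (2.80 ± 0.29) and Stab1 (2.84 ± 0.30).

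Neuronal transcripts were lower at day 2. Of 16 genes of synaptic transmission 12 fell (14 adjusted over the list alone), with a median log2 change of -0.53 (camera adjusted p = 2.07e-07, adjusted p = 0.123 with an estimated correlation). Synaptophysin, Syp, went from 678 ± 10.8 to 442 ± 30.6 CPM and the postsynaptic scaffold Dlg4 from 714 ± 9.93 to 491 ± 27.9. Among inhibitory neuron genes 7 of 10 fell (7 adjusted over the list alone; median -0.74, camera adjusted p = 1.05e-05, adjusted p = 0.148 with an estimated correlation). Among them were the neuropeptides Sst (-1.02 ± 0.13), Vip (-0.77 ± 0.14) and Npy (-0.95 ± 0.17). Immediate early genes, which report recent neuronal activity, fell in 7 of 13 cases (8 adjusted over the list alone; median -0.69, camera adjusted p = 4.64e-05, adjusted p = 0.28 with an estimated correlation). Nr4a1 changed by -1.60 ± 0.16, Egr4 by -1.50 ± 0.20 and Npas4 by -1.87 ± 0.24, while Jun rose by 0.95 ± 0.21. The other leading genes by size were Tgm1 (9.70 ± 0.43), Arg1 (9.17 ± 0.70), Slfn4 (849-fold, interval 234 to 7014) and Mmp3 (at least 223-fold) upward and Gucy2g (-2.65 ± 0.23), Fam227b (-2.01 ± 0.33), Lemd1 (-1.95 ± 0.21), Kirrel2 (-1.77 ± 0.33), Amn (-1.76 ± 0.35), Myl4 (-1.72 ± 0.36) and Fmod (-1.66 ± 0.39) downward. Without day 2 replicate 2, Fmod (adjusted p = 0.058), Jun (0.0538) and Myl4 (0.055) missed the threshold, as did Mmp3 without control replicate 3, day 2 replicate 2 or day 2 replicate 3 (0.0552 to 0.0605). With limma voom, Mmp3 (adjusted p = 0.116) and Myl4 (0.0585) were not called.

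At day 6 after injury, genes of lipid-handling phagocytes stood out in the cortex. Spp1, the secreted phosphoprotein osteopontin, stood at 2363 ± 1641 CPM against 3.32 ± 0.387 in controls (log2 change 9.48 ± 0.83, adjusted p = 9.94e-04; chromosome 5, 104435118 to 104441050), and the phagocyte membrane protein Gpnmb at 394.5 ± 224 against 1.15 ± 1.02 (8.45 ± 0.87, adjusted p = 1.91e-03; chromosome 6, 49036546 to 49070929). Apoe, the apolipoprotein that carries cholesterol in brain, went from 1744 ± 209.6 to 6317 ± 1369 CPM (adjusted p = 1.53e-05). Genes of cholesterol synthesis fell. Of 18151 genes tested, 1873 changed, 1440 up and 433 down. Of these, 1062 changed by at least 2-fold, 972 up and 90 down, and 941 passed an adjusted p of 0.01.

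Of 19 phagocyte and lipid-handling genes 18 rose at day 6 (19 adjusted over the list alone), with a median log2 change of 3.21 (camera adjusted p = 8.64e-71). Examples are the lectin receptor Clec7a (6.75 ± 0.44), the cholesterol exporter Abca1 (2.28 ± 0.17) and Cst7 (5.38 ± 0.50). Lpl did not pass the test. All 17 reactive astrocyte genes were still raised (17 adjusted over the list alone), with a median of 2.51 (camera adjusted p = 6.59e-50). Among them were Osmr (2.42 ± 0.18) and Gfap (2.75 ± 0.21, 1375 ± 164 CPM). Complement rose in 9 of 11 genes (10 adjusted over the list alone; median 2.84, camera adjusted p = 2.05e-42). C3 changed by 5.40 ± 0.37 and C1qb by 3.06 ± 0.22. Of 15 genes of cholesterol biosynthesis 14 fell (14 adjusted over the list alone), all but Fdps, with a median of -0.72 (camera adjusted p = 7.37e-23), among them the enzymes Msmo1 (-0.95 ± 0.09) and Cyp51 (-0.80 ± 0.09) and the regulator Insig1 (-1.06 ± 0.11). These 4 lists were also called with an estimated correlation (adjusted p = 0.0305 to 0.0322).

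Proteases and their inhibitors rose in 12 of 15 cases at day 6 (14 adjusted over the list alone; median 2.78, the same at the bounds, camera adjusted p = 2.84e-21, adjusted p = 0.0868 with an estimated correlation). The macrophage elastase Mmp12 was 3663-fold higher (interval 1253 to 17767, 3 counts in the controls), Timp1 rose by 3.24 ± 0.30 and Mmp2 by 2.05 ± 0.25. Extracellular matrix genes rose in 11 of 17 cases (16 adjusted over the list alone; median 1.85, camera adjusted p = 2.88e-20, adjusted p = 0.102 with an estimated correlation). Among them were Col6a1 (0.85 ± 0.14), Sparc (1.25 ± 0.19) and the crosslinking enzyme Lox (3.74 ± 0.58). The list mean was 71.7, 191 and 135 CPM in the day 6 libraries and 37.7, 28.5 and 27.4 in controls. Genes of meningeal and perivascular fibroblasts rose in 3 of 9 cases (4 adjusted over the list alone; median 0.73, camera adjusted p = 3.31e-03, adjusted p = 0.311 with an estimated correlation and 0.0538 with fry), with list means of 15.9, 30.3 and 21.1 CPM against 15.1, 7.25 and 7.03. Mural cell genes rose in 3 of 9 (6 adjusted over the list alone; median 0.57, camera adjusted p = 4.59e-04, adjusted p = 0.272 with an estimated correlation). Homeostatic microglia genes rose in 10 of 12 cases (12 adjusted over the list alone; median 1.02, camera adjusted p = 9.39e-20, adjusted p = 0.0868 with an estimated correlation). Fcrls changed by 2.38 ± 0.15. Of 20 cell cycle genes 14 were raised (19 adjusted over the list alone; median 1.58, camera adjusted p = 8.84e-16, adjusted p = 0.129 with an estimated correlation). Cdk1 changed by 4.07 ± 0.45.

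The other leading genes at day 6 were Mmp3 (at least 302-fold higher), Atp6v0d2 (598-fold, interval 165 to 4944), Rny1 (8.42 ± 0.71), Mmp13 (8.03 ± 1.27) and Msr1 (8.01 ± 0.67) upward, and Dcc (-2.03 ± 0.54), Zfp871 (-1.87 ± 0.37), Dok6 (-1.86 ± 0.46), Aff2 (-1.81 ± 0.30), Fam227b (-1.65 ± 0.32), Stk26 (-1.57 ± 0.39), Etnppl (-1.55 ± 0.28) and Rspo2 (-1.50 ± 0.40) downward. Single libraries weighed on this comparison: the count fell to 1156 without control replicate 2, 1138 without control replicate 3, 1005 without day 6 replicate 2 and 1131 without day 6 replicate 3. Dok6 was not called without any 1 of the 3 control replicates (adjusted p = 0.0547 to 0.0681). Dcc and Mmp3 were not called without any 1 of the 3 controls, day 6 replicate 2 or day 6 replicate 3 (0.0583 to 0.0961 and 0.0576 to 0.0922). Stk26 was not called without control replicate 2, control replicate 3 or any 1 day 6 replicate (0.0821 to 0.102), nor Rspo2 without control replicate 1, control replicate 2 or any 1 day 6 replicate (0.069 to 0.183). Limma voom did not call Mmp12 (adjusted p = 0.176), Mmp13 (0.322), Mmp3 (0.179), Atp6v0d2 (0.117), Msr1 (0.0533), Lox (0.0516), Stk26 (0.0607) or Rspo2 (0.126).

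Between days 2 and 6 in the cortex, transcripts of reactive astrocytes, cytokines and neutrophils became fewer, and some transcripts of lipid handling and of neurons became more abundant. Cxcl1, which attracts neutrophils, was lower at day 6 than at day 2 (log2 change -5.78 ± 0.43, 18.8 ± 5.83 to 0.339 ± 0.118 CPM), as were Ccl12 (-5.02 ± 0.33), Ccl2 (-4.87 ± 0.47), Lcn2 (-4.79 ± 0.40), Cxcr2 (-4.99 ± 0.46) and S100a9 (-4.60 ± 0.43). Apoe (2.23 ± 0.16), the apolipoprotein Apoc1 (4.00 ± 0.46), Gpnmb (4.21 ± 0.66) and the integrin Itgax (3.65 ± 0.58) were higher. In all, 2099 of 18151 genes differed between the times, 962 higher and 1137 lower at day 6. Of these, 628 differed by at least 2-fold, 201 higher and 427 lower at day 6, and 776 passed an adjusted p of 0.01.

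Reactive astrocyte genes were lower at day 6 than at day 2 in 14 of 17 cases (15 adjusted over the list alone; median log2 change -1.57, camera adjusted p = 1.12e-40). Among them were Ptx3 (-3.60 ± 0.28), Cp (-2.30 ± 0.20) and Steap4 (-3.56 ± 0.32). Cytokines and chemokines were lower in 12 of 18 cases (13 adjusted over the list alone; median -2.61, the same at the bounds, camera adjusted p = 3.04e-21), neutrophil genes in 7 of 10 (7 adjusted over the list alone; median -2.30, the same at the bounds, camera adjusted p = 2.04e-10) and interferon-stimulated genes in 14 of 20 (19 adjusted over the list alone; median -1.22, camera adjusted p = 1.52e-16). Ifitm3 changed by -1.75 ± 0.22. These 4 lists were also called with an estimated correlation (adjusted p = 0.0423 to 0.049). Cell cycle genes were lower in 18 of 20 cases (20 adjusted over the list alone; median -1.53, camera adjusted p = 8.56e-21, adjusted p = 0.0843 with an estimated correlation). Mcm6 changed by -2.04 ± 0.22. Leukocyte trafficking genes were lower in 6 of 14 cases (6 adjusted over the list alone; median -0.58, camera adjusted p = 8.4e-07, adjusted p = 0.114 with an estimated correlation). Ccr2 changed by -2.49 ± 0.31. Monocyte genes were lower in 3 of 11 cases and higher in 1, Lyz2 (2.39 ± 0.49; 4 and 2 adjusted over the list alone), and the list was not called (median -1.27, camera adjusted p = 0.0837; 0.0253 to 0.0319 without day 2 replicate 1, day 6 replicate 2 or day 6 replicate 3). The list was called as well with a replicate block, with no filter and in a fit of the compared groups alone. Its mean CPM, to which Lyz2 adds most, was 34.3, 50.1 and 42.4 at day 2 and 56.7, 175 and 115 at day 6. Phagocyte and lipid-handling genes were higher in 9 of 19 cases (11 adjusted over the list alone; median 1.08, camera adjusted p = 1.72e-16, adjusted p = 0.162 with an estimated correlation). Leading members were the protease Ctsd (1.81 ± 0.23) and the lipid receptor Trem2 (1.57 ± 0.26). Cholesterol biosynthesis was lower in 8 of 15 genes (12 adjusted over the list alone; median -0.44, camera adjusted p = 2.4e-08, adjusted p = 0.07 with an estimated correlation). Inhibitory neuron genes were higher in 4 of 10 cases (5 adjusted over the list alone; median 0.47, camera adjusted p = 2.67e-05, adjusted p = 0.162 with an estimated correlation). Vip changed by 0.85 ± 0.14, Npy by 0.85 ± 0.17 and Sst by 0.62 ± 0.13. Synaptic genes were higher in 8 of 16 (12 up and 1 down adjusted over the list alone; median 0.39, camera adjusted p = 3.75e-05, adjusted p = 0.173 with an estimated correlation). Examples were Shank1 (0.79 ± 0.14) and Dlg4 (0.48 ± 0.09).

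The other leading genes between the times were Col10a1 (7.16 ± 1.36), Atp6v0d2 (5.67 ± 0.79), Rny1 (4.17 ± 0.50), Mmp13 (4.03 ± 0.92) and Mmp12 (3.99 ± 0.70) upward and Selp (-5.61 ± 0.47) and Slfn4 (-4.66 ± 0.46) downward. Without day 2 replicate 3 the count was 1245, without day 6 replicate 1 it was 1273 and without day 6 replicate 3 it was 910. Col10a1 was not called without any 1 of the 3 day 2 replicates (adjusted p = 0.0531 to 0.0648), Mmp12 without day 2 replicate 2 or day 6 replicate 3 (0.0528 to 0.0551), and Mmp13 and Lyz2 without any 1 day 2 replicate or day 6 replicate 3 (0.0831 to 0.118 and 0.0532 to 0.0896). Limma voom did not call Col10a1 (adjusted p = 0.337), Mmp13 (0.227) or Atp6v0d2 (0.129).

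**Figure D1:**
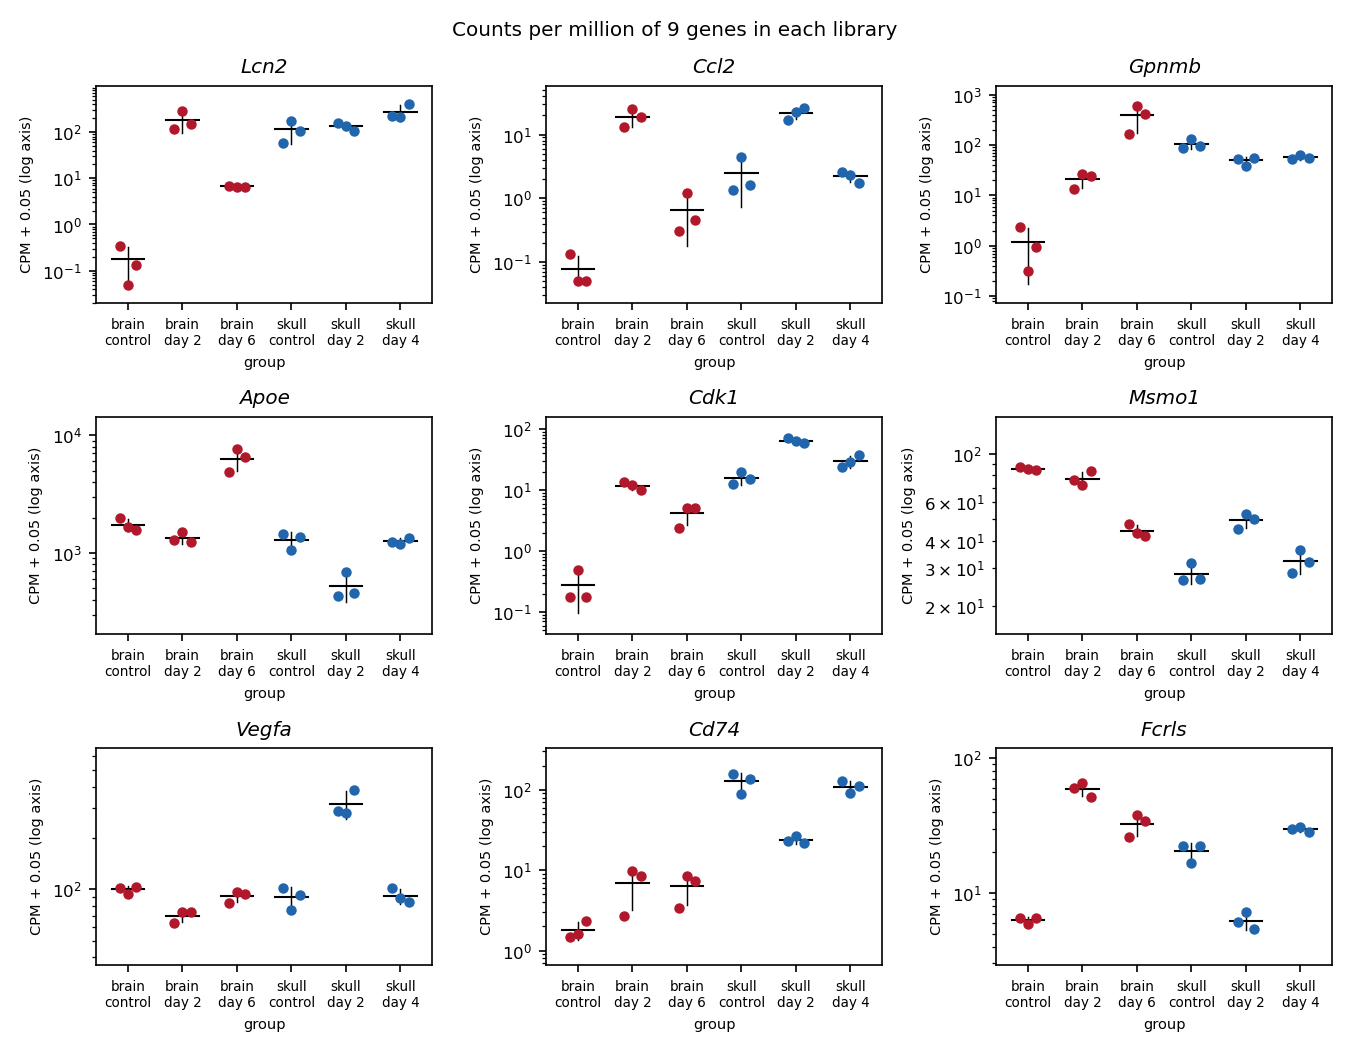
CPM (with 0.05 added, log axis) of 9 genes in each of the 18 libraries, red for brain and blue for skull; horizontal lines are group means and vertical lines the SD (n = 3). Lcn2 and Ccl2 peaked at day 2 in brain, Gpnmb and Apoe were highest there at day 6, and Vegfa was highest in skull at day 2.

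In the skull, day 2 after injury brought cytokine transcripts, glycolytic genes and proteases up, and genes of antigen presentation and of the B lineage down. Vegfa, the vascular growth factor induced by low oxygen, rose from 90.4 ± 13.3 to 317 ± 58.0 CPM (log2 change 1.81 ± 0.15, adjusted p = 9.04e-05; chromosome 17, 46016993 to 46032369). The collagenase Mmp13 rose from 1149 ± 159 to 13770 ± 3208 CPM (3.58 ± 0.24, adjusted p = 4.23e-05), and Arg1, the arginase of alternatively activated myeloid cells, from 0.565 ± 0.374 to 81.3 ± 18.5 (7.15 ± 0.44, adjusted p = 5.11e-05). Cd74, the invariant chain of MHC class II, fell from 127 ± 35.2 to 23.8 ± 2.70 CPM (-2.42 ± 0.22, adjusted p = 1.89e-04; chromosome 18, 60803848 to 60812652). Of 17450 genes tested, 6007 changed, 3106 up and 2901 down. Of these, 2187 changed by at least 2-fold, 786 up and 1401 down, and 3156 passed an adjusted p of 0.01. Without skull control replicate 3, 4024 genes changed.

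Of 16 genes of hypoxia and glycolysis 15 rose (15 adjusted over the list alone), with a median log2 change of 1.37 (camera adjusted p = 1.09e-15), and this list alone among those called was also called with an estimated correlation (adjusted p = 0.046). Pgk1 (1.49 ± 0.13), Ldha (1.18 ± 0.12) and the carbonic anhydrase Car9 (2.60 ± 0.27) rose, and Aldoa did not pass the test. All 20 cell cycle genes rose (20 adjusted over the list alone; median 1.46, camera adjusted p = 4.79e-23, adjusted p = 0.227 with an estimated correlation). Examples were the cyclins Ccnb1 (2.05 ± 0.17) and Ccna2 (1.61 ± 0.15). Proteases and inhibitors rose in 12 of 15 cases (12 adjusted over the list alone; median 1.28, camera adjusted p = 5.04e-14, adjusted p = 0.0804 with an estimated correlation). Among them were the urokinase Plau (1.52 ± 0.13), its receptor Plaur (2.07 ± 0.22) and Timp1 (3.12 ± 0.30). Cytokines and chemokines rose in 12 of 18 cases (14 up and 1 down adjusted over the list alone; median 2.64, the same at the bounds, camera adjusted p = 5.14e-09, adjusted p = 0.26 with an estimated correlation). Leading members were Il11 (4.53 ± 0.47), Cxcl1 (3.69 ± 0.42), Lif (2.42 ± 0.28) and Cxcl5 (4.54 ± 0.53). Antioxidant and metal response genes rose in 8 of 10 cases (8 adjusted over the list alone; median 0.85, camera adjusted p = 5.14e-07, adjusted p = 0.11 with an estimated correlation). The haem oxygenase Hmox1 changed by 2.66 ± 0.28 and Txnrd1 by 0.96 ± 0.08. Genes of cholesterol biosynthesis rose in 12 of 15 cases (14 adjusted over the list alone; median 0.75, camera adjusted p = 6.39e-07, adjusted p = 0.281 with an estimated correlation). Cyp51 changed by 1.58 ± 0.19 and Hmgcs1 by 0.85 ± 0.11.

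All 7 measured MHC class II genes fell (7 adjusted over the list alone; median log2 change -1.68, camera adjusted p = 3.54e-08, adjusted p = 0.11 with an estimated correlation). Among them were H2-Eb1 (-2.34 ± 0.25) and H2-Aa (-2.49 ± 0.33). B lineage genes fell in 8 of 11 cases (10 adjusted over the list alone; median -2.11, camera adjusted p = 1.92e-05, adjusted p = 0.321 with an estimated correlation). Ms4a1 changed by -2.46 ± 0.35 and Pax5 by -2.34 ± 0.41. T and NK cell genes fell in 6 of 10 cases (6 adjusted over the list alone; median -1.12, camera adjusted p = 8.32e-03, adjusted p = 0.387 with an estimated correlation). Plasma cell genes went both ways, 4 up and 3 down of 7 (the same adjusted over the list alone), and the list was not called (camera adjusted p = 0.801). Genes named for homeostatic microglia, which other macrophages share in part, fell in 6 of 12 cases (6 adjusted over the list alone; median -0.82, camera adjusted p = 3.02e-03, adjusted p = 0.11 with an estimated correlation). Fcrls went from 20.4 ± 3.22 to 6.17 ± 0.911 CPM and Cx3cr1 changed by -1.25 ± 0.12. Haemoglobin genes took 1.5% to 2.13% of counts in skull controls and 0.165% to 1.01% at day 2, and erythroid genes fell in 5 of 11 cases (5 adjusted over the list alone; median -1.62, camera adjusted p = 2.46e-04, adjusted p = 0.387 with an estimated correlation). Epb42 changed by -3.04 ± 0.51 and Hemgn by -2.43 ± 0.45.

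Transcripts of neurons were lower in injured skull. Of 16 synaptic genes 15 fell (15 adjusted over the list alone; median log2 change -2.17, camera adjusted p = 1.04e-08, adjusted p = 0.26 with an estimated correlation), and Slc17a7 went from 46.8 ± 21.8 to 3.86 ± 1.31 CPM. The median of 53 neuronal genes stood at 10.4%, 2.97% and 8.0% of its brain control level in the 3 skull controls and at 0.871% to 1.82% in the day 2 libraries. The 8 genes with the largest falls were all at least 4-fold higher in brain controls than in skull controls: Gpr26 (287-fold lower, interval 79.2 to 2379), Mpped1 (-5.86 ± 0.91), the glutamate receptor subunit Grin2b (-5.76 ± 1.01), Calb1 (-5.48 ± 1.26), Cpne6 (-5.13 ± 1.22), Hpcal4 (-5.01 ± 1.08), Ddn (-4.89 ± 1.01) and Tmem132b (-4.89 ± 1.12). With all genes at least 4-fold higher in brain controls left out, a choice made after seeing the data, 4952 genes changed, 60.5% of them upward against 51.7% of all 6007. Choroid plexus transcripts were uneven: Ttr, the transthyretin of the choroid plexus, stood at 74.4, 7631 and 1487 CPM in the 3 day 2 libraries against 3.64 ± 2.04 in controls (log2 change 9.68 ± 2.06), and 3 of 9 choroid plexus genes rose (6 adjusted over the list alone; median 4.54, camera adjusted p = 0.0213, adjusted p = 0.561 with an estimated correlation, 0.106 with fry and 0.0535 without control replicate 1). The mean of skeletal muscle genes was 439, 85.3 and 310 CPM in the controls and 1.97, 25.1 and 98.8 CPM at day 2. None of its 11 genes passed the test (0 adjusted over the list alone; median -3.06, camera adjusted p = 8.32e-03, adjusted p = 0.561 with an estimated correlation and 0.0954 with fry).

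The other leading risers in skull at day 2 were the neutrophil attractants Cxcl3 (at least 86.5-fold higher) and Cxcl2 (670-fold, interval 120 to 26501), the cytokine Il6 (6.84 ± 1.06), Saa3 (6.78 ± 0.77), Htr2c (7.18 ± 1.95) and Drc7 (6.46 ± 1.78). Whether Htr2c and Drc7 went with the uneven choroid plexus transcripts was not tested. Drc7 was not called without any 1 of the 3 skull controls (adjusted p = 0.0883 to 0.105), Htr2c without any 1 control or day 2 replicate 3 (0.0531 to 0.102), Ttr without control replicate 1 or 3 (0.0514 to 0.0552), Calb1 without day 2 replicate 1 or 3 (0.0541 to 0.0586) and Cpne6 without day 2 replicate 1 (0.0527). Limma voom did not call these 5 genes (adjusted p = 0.337, 0.438, 0.117, 0.295 and 0.12), nor Cxcl2 (0.0659), Gpr26 (0.113), Grin2b (0.148), Hpcal4 (0.117), Ddn (0.0818) and Tmem132b (0.13).

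**Figure D2:**
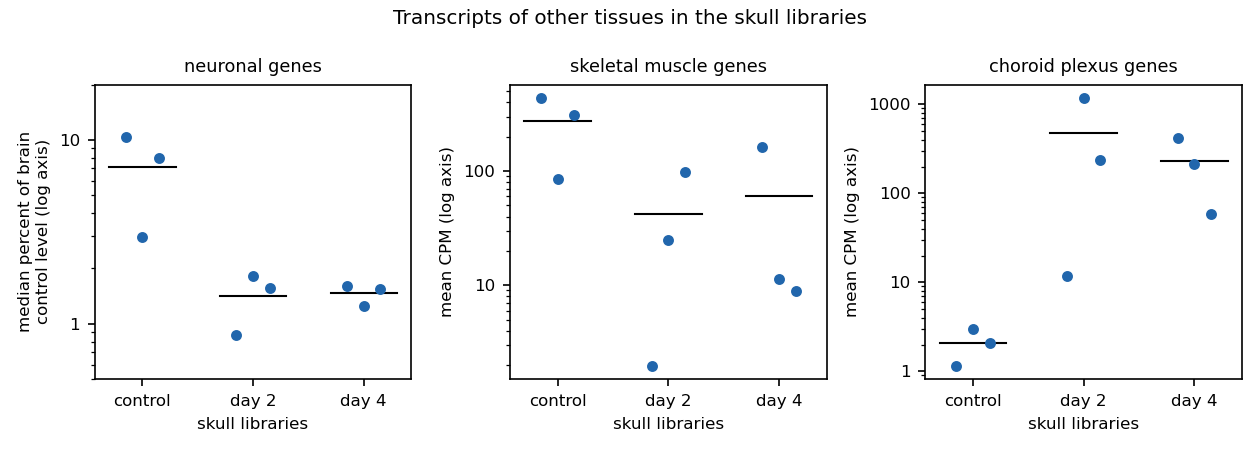
Levels of transcripts of other tissues in each skull library (points) with the group mean (line), on log axes: neuronal genes as the median percent of their brain control level, and skeletal muscle and choroid plexus genes as mean CPM, the last without Aqp1 and Otx2. Neuronal genes lay at 2.97% to 10.4% in controls and at 0.871% to 1.82% in injured skull.

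At day 4 the skull carried more transcripts of monocytes and granulocytes than control skull, and more of some genes of osteocytes and osteoblasts. The chemokine receptor Ccr2 rose from 38.4 ± 3.32 to 110.4 ± 11.4 CPM (log2 change 1.52 ± 0.10, adjusted p = 4.17e-04; chromosome 9, 124101950 to 124113557). Camp, an antimicrobial peptide of granulocyte precursors, rose from 75.5 ± 10.5 to 324 ± 128 CPM (adjusted p = 8.50e-03), and the osteocyte peptidase Phex from 32.0 ± 11.4 to 141 ± 27.0 (2.13 ± 0.27, adjusted p = 8.50e-03). Of 17450 genes tested, 1853 changed, 1018 up and 835 down. Of these, 730 changed by at least 2-fold, 224 up and 506 down, and 148 passed an adjusted p of 0.01. The day 4 calls rest on skull control replicate 3: without it 10 genes changed, 5 in each direction, and of the 31 called changes named for this comparison the one in Ccr2 alone still passed, the others reaching an adjusted p of 0.0542 or more.

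Monocyte genes rose in 8 of 11 cases at day 4 (10 adjusted over the list alone; median log2 change 0.97, camera adjusted p = 4.75e-13). Irf8 changed by 0.97 ± 0.12, Plac8 by 1.44 ± 0.21 and Lyz2 by 1.07 ± 0.19. This list alone among those called was also called with an estimated correlation (adjusted p = 0.0432). Granulocyte precursor genes rose in 9 of 11 cases (11 adjusted over the list alone; median 1.80, camera adjusted p = 4.95e-18, adjusted p = 0.175 with an estimated correlation). Among them were Chil3 (2.03 ± 0.26), Gfi1 (1.80 ± 0.26) and Ngp (1.94 ± 0.30). Genes of mature neutrophils rose in 7 of 12 cases (9 adjusted over the list alone; median 1.06, camera adjusted p = 1.36e-10, adjusted p = 0.222 with an estimated correlation). S100a9 went from 693 ± 180.1 to 2139 ± 636 CPM. Megakaryocyte and platelet genes rose in 6 of 10 cases (10 adjusted over the list alone; median 1.20, camera adjusted p = 7.65e-10, adjusted p = 0.25 with an estimated correlation). Itgb3 changed by 1.37 ± 0.15. Osteocyte genes rose in 4 of 6 cases (4 adjusted over the list alone; median 1.01, camera adjusted p = 3.43e-06, adjusted p = 0.145 with an estimated correlation). Dmp1 changed by 1.02 ± 0.15 and Sost, an inhibitor of bone formation, by 1.71 ± 0.28. Osteoblast genes rose in 4 of 11 cases (8 adjusted over the list alone; median 0.73, camera adjusted p = 2.64e-06, adjusted p = 0.26 with an estimated correlation). Ibsp changed by 1.61 ± 0.33 and Col1a1 by 1.02 ± 0.25. Heat shock genes fell in 5 of 11 cases (7 adjusted over the list alone; median -0.71, camera adjusted p = 4.86e-07, adjusted p = 0.175 with an estimated correlation). Hsp90aa1 changed by -0.81 ± 0.09 and Hsph1 by -1.49 ± 0.19. The largest rises besides were Ttr (8.62 ± 1.98), Saa3 (3.60 ± 0.78), Car12 (3.45 ± 0.39), Cldn2 (2.98 ± 0.58), Itgb2l (2.23 ± 0.38) and Ffar2 (2.09 ± 0.47). Whether Cldn2 went with Ttr and the other choroid plexus transcripts was not tested.

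The 8 largest falls at day 4 were again in genes at least 4-fold higher in brain controls: Gpr26 (-6.60 ± 1.10), Grin2b (-5.64 ± 1.01), Ly6h (-5.54 ± 1.15), Mpped1 (-5.47 ± 0.89), Kcnk9 (-5.40 ± 1.15), Gad2 (-5.24 ± 1.32), Calb1 (-5.20 ± 1.24) and Dpp10 (-4.87 ± 0.79). Of 16 synaptic genes 9 fell (15 adjusted over the list alone; median log2 change -2.14, camera adjusted p = 3.07e-15, adjusted p = 0.175 with an estimated correlation), and neuronal genes stood at 1.25% to 1.61% of their brain control level in the day 4 libraries. Without genes at least 4-fold higher in brain controls, chosen after seeing the data, 1031 genes changed, 782 up and 249 down, so that 75.8% rose against 54.9% of the full count. Without day 4 replicate 2, 590 genes changed and 11 of the named calls were lost, and without day 4 replicate 3 these were 237 and 15. Lost in both cases were Gpr26, Grin2b, Ly6h, Kcnk9, Gad2, Calb1, Saa3, Ffar2, Col1a1 and Ttr, besides Cldn2 in the first and Mpped1, Dpp10, Ibsp, Lyz2 and Sost in the second (adjusted p = 0.0514 or more). Calb1, Gad2, Kcnk9, Ly6h and Ttr were lost without day 4 replicate 1, Calb1, Cldn2, Gad2, Ibsp, Saa3 and Ttr without control replicate 1, and Cldn2, Saa3 and Ttr without control replicate 2. Limma voom called none of the 8 largest falls (adjusted p = 0.0912 to 0.421), nor Ttr (0.187), Cldn2 (0.122) or Saa3 (0.094). DESeq2 called 2864 genes, and a fit of the 2 groups alone 1004 with 42.4% upward.

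Between days 2 and 4, hypoxia and cytokine transcripts became fewer in the skull, and those of antigen presentation and of the B lineage became more abundant. Arg1 was lower at day 4 than at day 2 (log2 change -7.02 ± 0.44, 81.3 ± 18.5 to 0.615 ± 0.345 CPM), as were Mmp3 (-5.59 ± 0.56), Il6 (-4.81 ± 0.90) and the lubricin gene Prg4 (-4.99 ± 0.58). Sost went from 0.602 ± 0.182 to 7.83 ± 0.746 CPM (3.68 ± 0.32, adjusted p = 1.69e-04), and Bglap2, which encodes osteocalcin, from 83.4 ± 22.7 to 780.3 ± 85.5 (3.23 ± 0.50, adjusted p = 5.04e-03). Of 17450 genes 3772 differed, 1842 higher and 1930 lower at day 4. Of these, 944 differed by at least 2-fold, 536 higher and 408 lower, and 1521 passed an adjusted p of 0.01.

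All 16 genes of hypoxia and glycolysis were lower at day 4 than at day 2 (16 adjusted over the list alone; median log2 change -1.57, camera adjusted p = 1.12e-32). Among them were Vegfa (-1.79 ± 0.15) and Bnip3 (-2.27 ± 0.19). Genes of homeostatic microglia were higher in 7 of 12 cases (8 adjusted over the list alone; median 0.83, camera adjusted p = 1.24e-08). Fcrls changed by 2.26 ± 0.16. Border macrophage genes were higher in 6 of 9 (6 adjusted over the list alone; median 0.81, camera adjusted p = 8.46e-06). Mrc1 changed by 1.12 ± 0.10. These 3 lists were also called with an estimated correlation (adjusted p = 0.00629, 0.0185 and 0.0456). All 7 MHC class II genes were higher (7 adjusted over the list alone; median 1.71, camera adjusted p = 4.19e-10, adjusted p = 0.0641 with an estimated correlation). Cd74 changed by 2.20 ± 0.22. Proteases and inhibitors were lower in 10 of 15 cases and higher in 1, Mmp8 (1.05 ± 0.24), with the same counts adjusted over the list alone (median -1.03, camera adjusted p = 2.29e-10, adjusted p = 0.0641 with an estimated correlation). Mmp13 was lower by -2.45 ± 0.23. B lineage genes were higher in 9 of 11 cases (11 adjusted over the list alone; median 1.80, camera adjusted p = 1.27e-06, adjusted p = 0.314 with an estimated correlation). Dntt changed by 3.33 ± 0.62 and Vpreb3 by 2.50 ± 0.49. Erythroid genes were higher in 5 of 11 (5 adjusted over the list alone; median 0.50, camera adjusted p = 5.78e-05, adjusted p = 0.358 with an estimated correlation). Hemgn changed by 3.27 ± 0.46 and Epb42 by 3.29 ± 0.51, while haemoglobin genes took 0.564% to 0.820% of counts at day 4, within the 0.165% to 1.01% of day 2. Cytokines and chemokines were lower in 10 of 18 (12 adjusted over the list alone; median -1.92, camera adjusted p = 7.72e-09, adjusted p = 0.277 with an estimated correlation). Il11 changed by -4.27 ± 0.46 and Ptgs2 by -3.55 ± 0.36. The other leading genes were Cilp2 (3.29 ± 0.25), Cytl1 (3.14 ± 0.45) and Kel (3.13 ± 0.58) upward and Cxcl3 (-5.76 ± 0.77), Cxcl2 (-5.32 ± 1.04), Prok2 (-5.31 ± 0.86) and Gipr (-5.25 ± 0.59) downward. Without day 2 replicate 1 or 3 the count was 2354 or 2299, and without day 4 replicate 1 or 3 it was 2294 or 2260. Mmp8 was not called without day 2 replicate 2 or 3 (adjusted p = 0.0582 to 0.0584). Limma voom did not call Cxcl2 (adjusted p = 0.133).

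**Figure D3:**
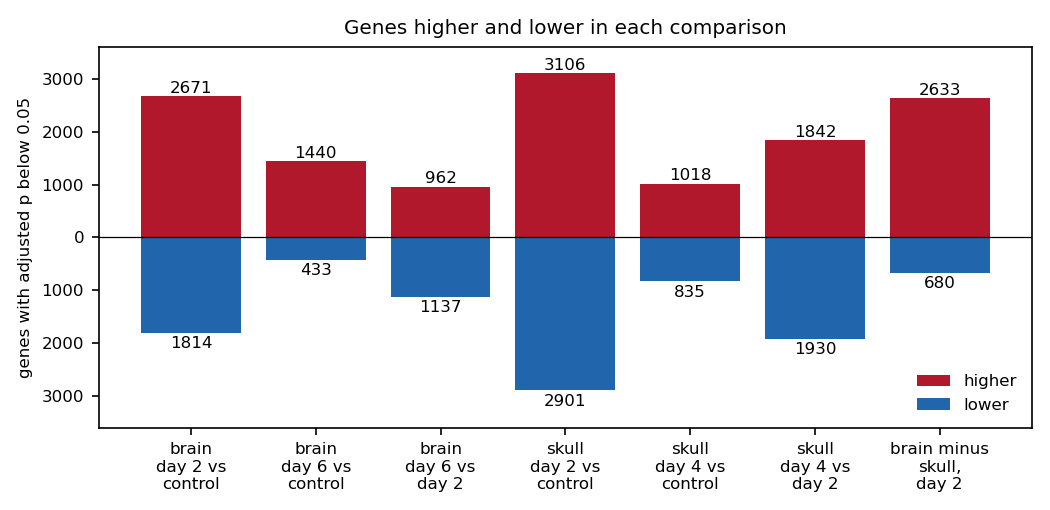
Genes with adjusted p below 0.05 (vertical axis) in 7 comparisons, higher in red above 0 and lower in blue below it. The total was highest in skull at day 2 (6007) and lowest in skull at day 4 (1853).

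Day 2 was the only time sampled in both tissues, and there the responses of brain and skull were compared gene by gene. Genes of reactive astrocytes, complement, monocytes, homeostatic microglia and leukocyte trafficking had the higher change in brain, while glycolytic and cholesterol genes had it in skull. C1qb, a subunit of the first complement component, went from 19.2 ± 1.97 to 118 ± 27.2 CPM in brain and from 65.3 ± 8.24 to 31.7 ± 1.75 in skull, a log2 difference of responses of 3.66 ± 0.23 (adjusted p = 4.84e-06). Vegfa went from 102 ± 4.84 to 71.0 ± 6.25 CPM in brain and from 94.3 ± 15.4 to 316 ± 58.9 in skull (-2.26 ± 0.21, adjusted p = 5.00e-05). The response differed in 3313 of 18863 genes, 2633 with the higher change in brain and 680 with the higher change in skull. Of these, 2190 differed by at least 2-fold, 2003 with the higher change in brain and 187 in skull, and 1402 passed an adjusted p of 0.01. The median difference over all genes was 0.20 with TMM scaling, and differences are to be read against it. Other scalings gave medians of 0.12 to 0.16 and 70.7% to 73.6% of the called genes with the higher change in brain, against 79.5%. The fit of all 18 libraries gave 0.08 and 63.6% of 4006 genes.

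Reactive astrocyte genes had the higher change in brain in 16 of 17 cases (17 adjusted over the list alone; median log2 difference 3.20, camera adjusted p = 9.51e-36). Steap4 rose from 0.280 ± 0.244 to 47.9 ± 13.1 CPM in brain and stood at 74.1 ± 1.62 and 102 ± 4.37 in skull, so that the larger change in brain began from a low level. For Lcn2 (10.30 ± 0.88) the skull levels were 118 ± 60.1 and 134 ± 24.5. Complement genes differed the same way in 10 of 12 cases (10 adjusted over the list alone; median 2.79, camera adjusted p = 5.69e-22). Leukocyte trafficking genes had the higher change in brain in 10 of 14 cases and the higher change in skull in 1, the stromal chemokine Cxcl12 (-0.69 ± 0.20, a call that single libraries end), with the same counts adjusted over the list alone (median 2.98, camera adjusted p = 4.91e-17). Ccr2 differed by 3.90 ± 0.34. Monocyte genes differed in 8 of 11 cases (8 adjusted over the list alone; median 3.19, camera adjusted p = 9.98e-14). Lyz2 changed by 4.10 ± 0.30. Homeostatic microglia genes differed in 7 of 12 (7 adjusted over the list alone; median 1.57, camera adjusted p = 1.3e-14), with Fcrls up in brain and down in skull (5.01 ± 0.23, adjusted p = 4.48e-07) and Cx3cr1 likewise (2.43 ± 0.20). Phagocyte and lipid-handling genes had the higher change in brain in 16 of 19 cases and the higher change in skull in 1, Fabp5 (-0.81 ± 0.20; 17 and 1 adjusted over the list alone; median 1.64, camera adjusted p = 1.42e-15). Cholesterol biosynthesis had the higher change in skull in 13 of 15 genes (14 adjusted over the list alone; median -1.08, camera adjusted p = 4.81e-21). Cyp51 changed by -1.74 ± 0.11 and Hmgcs1 by -1.40 ± 0.16. Hypoxia and glycolysis had the higher change in skull in 10 of 16 genes and in brain in 1, Hk2 (1.96 ± 0.35), with the same counts adjusted over the list alone (median -0.88, camera adjusted p = 4.97e-11). Pgk1 differed by -1.57 ± 0.16. These 8 lists were also called with an estimated correlation (adjusted p = 0.0116 to 0.0414).

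MHC class II genes differed in all 7 cases (7 adjusted over the list alone; median 4.46, camera adjusted p = 3.23e-08, adjusted p = 0.0519 with an estimated correlation). Cd74 stood at 1.79 ± 0.471 and 7.03 ± 3.82 CPM in brain controls and day 2 and at 133 ± 38.7 and 23.7 ± 2.58 in skull. All 9 border macrophage genes differed (9 adjusted over the list alone; median 3.33, camera adjusted p = 6.08e-11, adjusted p = 0.055 with an estimated correlation). Stab1 changed by 3.57 ± 0.29. Among the leading genes, Tgm1 (8.69 ± 0.84) had the higher change in brain and Car12 (-5.19 ± 0.38), Ankrd55 (-3.96 ± 0.36) and Gipr (-3.61 ± 0.67) had it in skull. Mylk2, Selp, H2-Aa and Ccl8 had no count in brain controls, Cxcr2 had 1 there and Grm5 none in skull at day 2, so that their fitted differences (10.93, 9.37, 8.76, 8.02, 8.13 and 9.85) depend on the prior count and bound nothing. From skull controls to day 2, counts fell for Mylk2 (2668 to 323), Grm5 (285 to 0), H2-Aa (569 to 102) and Ccl8 (285 to 237). They rose for Selp (475 to 646) and Cxcr2 (1063 to 1738). Whether the falls of Mylk2 and Grm5 went with the uneven muscle and neuronal transcripts in skull was not tested. Htr2c (-7.06 ± 1.81), Drc7 (-6.05 ± 1.80), Prlr (-5.80 ± 1.72), Enpp2 (-4.44 ± 1.15) and Fhad1 (-4.19 ± 1.09) changed more in skull, where their day 2 libraries were far apart (Htr2c 37.1 ± 42.7 CPM). Ttr was uneven over the same skull day 2 libraries (74.4, 7631 and 1487 CPM). Whether the rises of these genes went with those of the choroid plexus transcripts was not tested. With 1 library left out at a time, 8 of the named differences were lost at least once. These were Drc7 (adjusted p = 0.055 to 0.0997) and Prlr (0.0614 to 0.108) without any 1 library other than skull day 2 replicate 1, Mylk2 (0.0538 to 0.0793) without any 1 other than skull control replicate 2 and skull day 2 replicates 1 and 3, and Enpp2 (0.0534 to 0.0642) without any 1 other than brain control replicate 1 and the skull day 2 replicates. Htr2c was lost without brain control replicate 2, brain day 2 replicate 2 or any 1 skull control (0.0507 to 0.0692), Fhad1 without brain control replicate 2 or 3 or skull control replicate 1 or 3 (0.0506 to 0.0711), and Grm5 without brain control replicate 2 or 3 or skull control replicate 3 (0.0509 to 0.0523). Cxcl12 was lost without brain control replicate 2 or 3, brain day 2 replicate 1 or 3, skull control replicate 3 or any 1 skull day 2 replicate (0.0556 to 0.0763). Limma voom called Cxcl12 (adjusted p = 0.0196) and none of the other 7 (0.119 to 0.434). Without skull control replicate 3, 2185 genes differed, and with the genes at least 4-fold higher in brain controls left out, 2665 did.

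**Figure D4:**
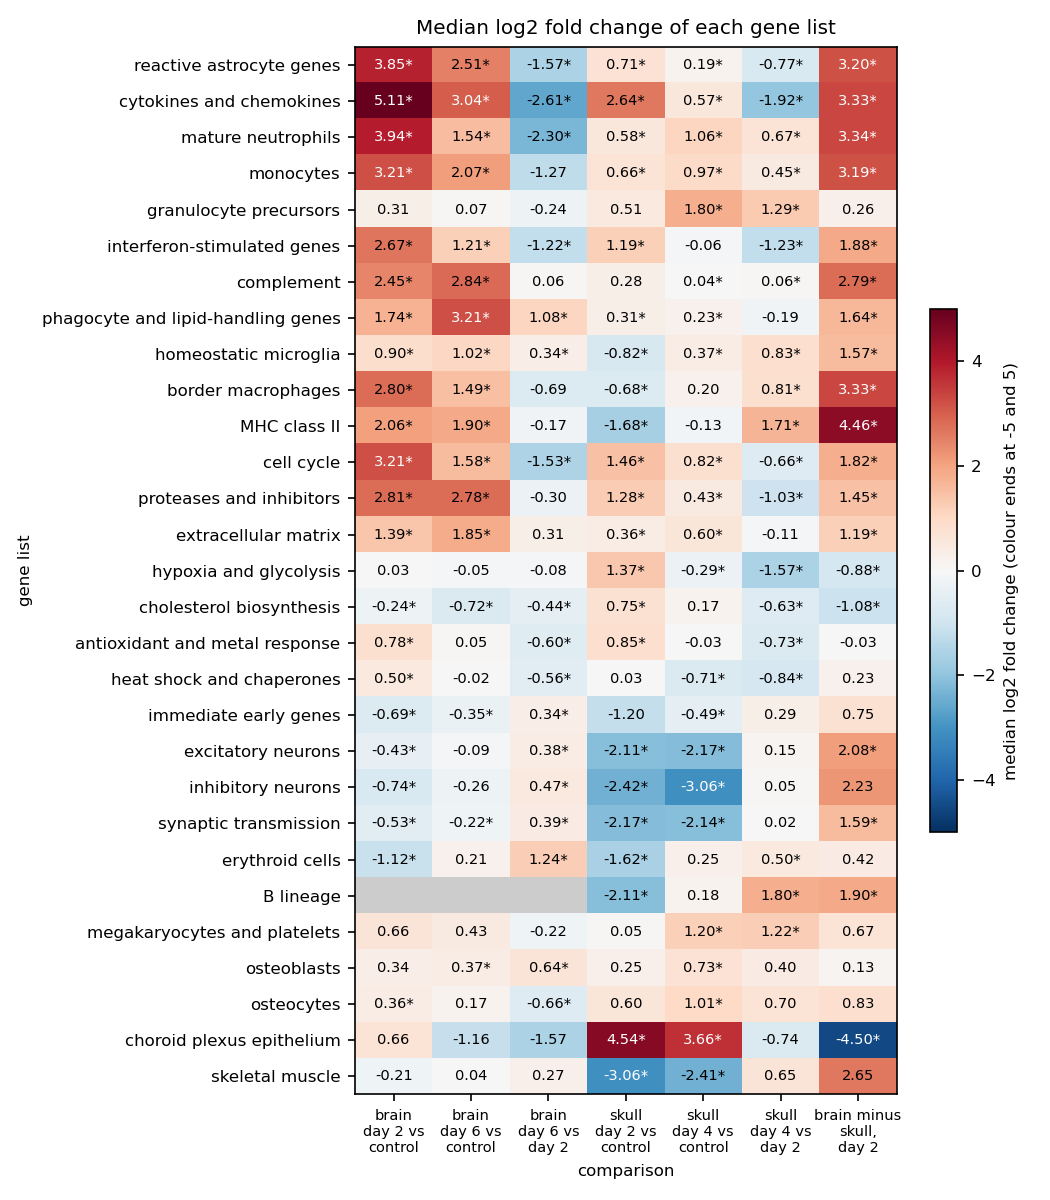
Median log2 fold change of 29 gene lists (vertical axis) in 7 comparisons (horizontal axis), red for higher and blue for lower, with colours ending at 5 in either direction; a star marks camera adjusted p below 0.05 with a preset correlation, and grey a list not tested. MHC class II had the highest median difference between brain and skull, 4.46.

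Many of the genes that changed at day 2 changed in the same direction in both tissues. Of 16250 genes tested in both, 1170 rose in brain and in skull, against 481 expected from the 2633 and 2968 that rose in each (odds ratio 5.26, two-sided Fisher exact p = 6.81e-264), and 782 fell in both, against 285 expected from 1678 and 2758 (odds ratio 5.56, p = 2.90e-201). Fewer went opposite ways than expected: 190 were higher in brain and lower in skull (447 expected), and 75 lower in brain and higher in skull (306 expected). Cdk1, Saa3, Arg1, Ccl2, Cxcl1 and Timp1 rose in both tissues, and Dlg4 and Slc17a7 fell in both. Of the 782 shared falls, 500 were in genes at least 4-fold higher in brain controls than in skull controls, Dlg4 and Slc17a7 among them, whereas 6 of the 1170 shared rises were. With such genes left out, a choice made after seeing the data, 1119 of 14647 genes rose in both (498 expected, odds ratio 4.66, two-sided Fisher exact p = 1.71e-219) and 265 fell in both (105 expected, odds ratio 3.61, p = 2.51e-51). At a change of at least 2-fold, 373 genes were shared. Without skull control replicate 3, 1469 genes were shared, against 1952 with all libraries. The 2 comparisons have no library in common, and genes are not independent replicates.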

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

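The tests of cortex carried into skull libraries, of its composition, of a single library, of a mixture over all genes and of the choroid plexus genes were chosen after the results were seen. The counts over other splits were planned. The tests of receptor segments and of genes private to a library were written before their own outcome, but for a pattern already seen in these data.

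The response at day 2 differed between brain and skull in 3313 genes and in 28 gene lists by the interaction test, of which 8 were also called with an estimated correlation. Of 100 splits that permuted injury within each tissue, 1, the real one, gave as many genes. The highest of the others, 1756, came from a split that left the skull libraries as they were. This cannot decide about chance for the count: a split that mixes injured and control libraries puts the injury response into the spread. Splits that mixed both tissues gave 0 genes, and the labelled splits with 1 tissue turned round were not among the 100. The list medians of the difference were 4.46 for MHC class II and 3.33 for border macrophages (adjusted p = 0.0519 and 0.055 with an estimated correlation), 1.57 for homeostatic microglia and -1.08 for cholesterol biosynthesis. Between the injury times, 2099 genes differed in brain and 3772 in skull. For the shared genes at day 2, 1952 in all, 1 of 200 pairs of splits, the real one, gave as many, which decides nothing about chance: other splits of a tissue called at most 30 genes, and the highest other count, 265, came from the labelled splits with 1 tissue turned round. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05, and 1 of the 10, the real split, gave the count in each comparison. The real counts and the highest of the others were 4485 and 30 in brain at day 2, 1873 and 0 at day 6, 2099 and 0 between these days, 6007 and 0 in skull at day 2, 1853 and 2 at day 4, 3772 and 0 between these days, and 12891 and 0 between the control groups.

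Neuronal transcripts were lower in injured skull than in skull controls, at a median of 10.4%, 2.97% and 8.0% of their brain control level in the 3 controls and 0.871% to 1.82% in the 6 injured libraries. Cortex carried into the control bone is a candidate explanation: across 1790 genes at least 4-fold higher in brain controls, the excess in skull controls followed the brain level (Spearman rho 0.806), and 91.3% of them were higher in skull controls. The excess is a difference in CPM, so a fall of such transcripts in the bone in proportion to their level could raise rho as well. The median excess differed between lists, with 0.991% of brain level for myelinating oligodendrocyte genes, 5.18% for neuronal genes and 8.69% for astrocyte genes. This goes against tissue of the same composition as the brain controls but does not exclude it. The injured libraries that were subtracted held the oligodendrocyte genes at a median of 1.40% to 3.80%. Before subtraction the 3 controls held them at 4.66%, 3.10% and 3.96%, below the neuronal level in replicates 1 and 3 but not in replicate 2. A single control library as the source cannot be told apart: the second highest, replicate 3 at 8.0%, is near the 7.90% that a mixture of replicates 1 and 2 would give, although replicate 2 at 2.97% also lay above the highest injured library. What also stays open is tissue of another composition, such as a surface layer poor in myelin, and a change of these transcripts in the bone with injury, which was not tested.

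Skull control replicate 3 lay between replicates 1 and 2 in 96.0% of the 3055 genes in which those differ by more than 0.5 on the log2 scale. The same measure was 8.75% to 88.2% in the other 17 libraries, highest in brain day 6 replicate 3. The day 4 count fell from 1853 to 10 without skull control replicate 3. Of all libraries left out singly, this one also gave the lowest counts for skull at day 2 (4024) and the difference of responses (2185). The same held for shared genes (1469) and the control groups (11652). A mixture of RNA or reads of the other 2, at 64.6% and 35.4%, is a candidate explanation: its residual was 1.94 times counting noise, against a lowest of 4.56 and a median of 6.54 among the other 17 libraries. A simulated pure mixture gave 0.65, but it was drawn from the observed counts of replicates 1 and 2 themselves. It thus lacked their counting noise, which the measure allows for. RNA mixed and then sequenced on its own would give a higher value, so 0.65 is no yardstick for it. The antigen receptor segments were too few to decide, since 14 were seen in replicate 3 and 7.14% of these, 1 segment, in neither other control. The genes with counts in replicate 3 alone, 0.469% against a lowest value of 0.430% among the other libraries, do not separate it from an independent library. An independent bone that happened to lie between the others stays open. Were replicate 3 a mixture, every comparison with skull controls would rest on 2 independent controls, and its p-values would understate the spread.

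Choroid plexus transcripts were high in most injured skull libraries, with Ttr at 74.4, 7631 and 1487 CPM at day 2 and 2627, 1364 and 370.4 CPM at day 4, against 1.72, 5.93 and 3.65 CPM in controls. Choroid plexus tissue carried into the libraries is a candidate explanation: relative to Ttr, the other marker genes varied with a median SD of 0.342 on the log2 scale over the 6 injured libraries, while their own levels varied with SDs of 2.01 to 2.40. A rise in the bone itself with injury cannot be told apart, since 3 of the 7 markers had every injured library above every control and the rest did not.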

How the results depend on the processing

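The fits without genes at least 4-fold higher in brain controls and with TMM factors within each tissue were chosen after the results were seen, and the other alternatives were planned. No named gene and no list described turned its direction under any alternative run, but the majority among called genes turned in 4 counts. With a 2-fold minimum the share higher went from 51.7% to 35.9% in skull at day 2, from 54.9% to 30.7% at day 4 and from 48.8% to 56.8% between these days. Between days 2 and 6 in brain it went from 45.8% to as much as 52.1%, without day 2 replicate 2, and in skull at day 4 it was 41.5% without control replicate 2. Over the list tests described, 1285 values under alternatives were computed, of which 1217 kept their side of the threshold, 51 lost the call and 17 gained one; for named genes these were 4206, 3927, 275 and 4. The causes of the changes below were not tested, except that stricter thresholds call fewer genes by construction. With at least a 2-fold change, the counts were 1637 and 1062 in brain at days 2 and 6, 628 between these days, 2187 and 730 in skull at days 2 and 4, 944 between these days, 2190 for the difference of responses and 373 for shared genes. At an adjusted p of 0.01 they were 2616, 941, 776, 3156, 148, 1521 and 1402 in the same order. For skull at day 4, DESeq2 gave 2864 genes, a replicate block 765, the 2 groups alone 1004 and the set without brain-enriched genes 1031. Whether the replicate numbers pair libraries is not known: no label ties them together, and the correlation of deviations from the group means exceeded 0.1 in 3 of 9 pairs of the same number in brain and 4 of 9 in skull, against 2 of 18 and 7 of 18 other pairs. Blocked by replicate number, the other counts were 4606 and 2050 in brain at days 2 and 6, 2326 between these days, 5085 in skull at day 2, 2876 between days 2 and 4, 3095 for the difference of responses and 12095 between the control groups, and named calls ended in 7 cases in skull at day 4, 2 in skull at day 2 and 4 in the difference of responses. Leaving out 1 library at a time gave 3136 to 4622 genes in brain at day 2, 1005 to 2091 at day 6 and 910 to 1948 between these days. In skull it gave 4024 to 6508 at day 2, 10 to 2537 at day 4 (10 without control replicate 3, 590 and 237 without day 4 replicates 2 and 3) and 2260 to 3057 between these days. The difference of responses ranged from 2185 (without skull control replicate 3) to 3979, the control groups from 11652 to 12998 and the shared genes from 1469 to 2164, with 1384 shared genes without brain-enriched genes. The lowest counts in skull at day 2, between the control groups and for shared genes also came without skull control replicate 3. The lists called ranged from 29 to 31 in brain at day 2, 30 to 33 at day 6 and 22 to 29 between these days, 24 to 34 in skull at day 2, 26 to 33 at day 4 and 23 to 29 between these days, 27 to 31 for the difference of responses and 39 to 40 for the control groups. With an estimated correlation 6, 4 and 6 lists were called in the brain comparisons, 1, 1 and 3 in the skull comparisons, 8 for the difference of responses and 5 for the control groups. With the mixed test of fry, 44 lists were called between days 2 and 6 in brain, 46 in skull at day 2, 41 between days 2 and 4 in skull and 49 for the difference of responses. Where a group is left with 2 libraries, its spread is pooled with the other groups. In the simulated data, genes with small counts were called less often: a 2-fold change in brain at day 2 was called in 25.8% of 31 genes below the median count and in 94.3% of 35 at or above it. Depth was not varied apart from the spread, which was larger for the former (median dispersion 0.0984 against 0.0141). The simulation changed few genes, so these shares are not the recovery in the data.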

Other observations

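The lists and values in this part were chosen after the results were seen.

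In skull at day 2, genes of bone moved in both directions. Of 15 genes of bone resorption and formation signals 8 rose and 3 fell (the same adjusted over the list alone; median log2 change 0.50, camera adjusted p = 0.0667, not called; 0.0464 and 0.0352 without control replicates 1 and 2, and 3.91e-03 with fry). Tnfsf11, the ligand that drives osteoclast formation, rose from 6.95 ± 2.77 to 69.3 ± 9.96 CPM (n = 3 each), while the bone morphogenetic protein Bmp4 fell by 0.80 on the log2 scale. Osteoblast genes were split, 2 up and 2 down of 11 (2 and 3 adjusted over the list alone; camera adjusted p = 0.141, and 0.0249 without day 2 replicate 3): the matrix proteins Ibsp (3.56 ± 0.36) and Spp1 (2.37 ± 0.23) rose, and Bglap2 (-2.49 ± 0.49) and Dlx5 (-0.51 ± 0.12) fell. Between days 2 and 4, 5 of the 11 were higher and 2 lower (the same adjusted over the list alone; median 0.40, camera adjusted p = 0.123, and 0.0398 and 0.0216 without day 2 replicate 1 and day 4 replicate 1), with Ibsp (-1.95 ± 0.33) and Spp1 (-1.51 ± 0.23) lower and Dlx5 (0.83 ± 0.12) higher.

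In brain at day 2, endothelial genes rose in 9 of 12 cases (10 adjusted over the list alone; median log2 change 0.90, camera adjusted p = 2.06e-06, adjusted p = 0.241 with an estimated correlation), Pecam1 from 18.3 ± 0.582 to 60.3 ± 11.8 CPM. Antioxidant and metal response genes rose in 7 of 10 (8 adjusted over the list alone; median 0.78, camera adjusted p = 1.13e-06, adjusted p = 0.0769 with an estimated correlation), Hmox1 by 5.36 ± 0.50 and Mt1 by 1.62 ± 0.14. Between days 2 and 6 that list was lower in 7 of 10 genes (7 adjusted over the list alone; median -0.60, camera adjusted p = 1.13e-08, adjusted p = 0.049 with an estimated correlation). Erythroid genes, which stand for blood left in the tissue as much as for cells within it, were higher at day 6 than at day 2 in 3 of 7 cases (5 adjusted over the list alone; median 1.24, camera adjusted p = 4.99e-07, adjusted p = 0.0423 with an estimated correlation), Hba-a1 by 1.52 ± 0.15. Day 2 was the low point: haemoglobin genes took 0.00679% to 0.00744% of counts in brain controls, 0.00254% to 0.00393% at day 2 and 0.00753% to 0.00782% at day 6.

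Genes of striatal neurons had uneven levels within the brain groups, with list means of 28.3, 73.6 and 93.6 CPM in the controls, 28.1, 19.0 and 166 CPM at day 2 and 22.9, 19.6 and 19.9 CPM at day 6. Interferon-stimulated genes in skull at day 2 had a list mean of 101 CPM in replicate 3 and of 35.9 and 38.0 CPM in replicates 1 and 2. Mitochondrial genes took 5.70% to 5.95% of counts in skull controls, 3.99% to 4.54% at day 2 and 3.94% to 5.60% at day 4.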
